A study of Homo sapiens with 16 samples.

How the data were processed

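RNA from cutaneous squamous cell carcinomas (cSCC, skin cancers that arise from keratinocytes) and from normal skin of the same patients had been sequenced, with 8 patients, 16 samples and 1 library per sample. Per the labels' protocols, RNA was taken from human tissue, DNA was removed and libraries were made with an Illumina mRNA kit. The labels give the molecule as polyA RNA, yet structural RNAs without a poly(A) tail took 10.4% to 39.7% of gene counts, and this conflict was not resolved. Per the series' design text, reads were 101 bp paired-end from a HiSeq instrument. That text speaks of skin organoids where the sample protocols speak of tissues, and the samples were treated here as tissue. Whether counting used strand is not given in the sources used here, so reads of antisense and overlapping genes may not be separated.

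The authors deposited estimated counts per transcript, 1 column per sample, with no normalization recorded. Per the submitters' processing notes, the tools named were Salmon 1.5.1 and the genome build hg38. The transcript annotation release and any filter are not given in the sources used here. Of 236186 transcript identifiers in the table, 203876 (86.3%) matched GENCODE release 29 by their identifier without version, and the other 32310 were left out of the gene tests. The matched transcripts held between 94.9% and 97.4% of the estimated counts of a library. A gene's value therefore covers its matched transcripts only and can be partial where later isoforms carry part of its reads. Estimated counts were summed to 58165 genes, rounded to whole numbers and given current symbols, which 57827 genes had in the symbol table. Coordinates are those of GENCODE release 29 on GRCh38. All sample columns of the table were used.

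Total estimated counts ran from 36.1 to 128.9 M (10 to the power 6) per library, with a median of 60.0 M. Nuclear protein-coding genes held between 28.1 and 84.0 M counts per library. The common dispersion of genes was 0.16, so that for abundant genes the spread between patients exceeded the counting error.

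Samples were grouped by their titles, and the patient number in the titles paired the 2 samples of a patient. The letters A to H stand for the 8 patient pairs. The pairing was checked with the 1000 most variable genes. Group-centred log2 CPM (counts per 10 to the power 6 counts) correlated at between 0.19 and 0.42 within patients, with a mean of 0.30, against a mean of -0.04 between patients. Each of the 8 tumours correlated best with the normal sample of its own patient, with a one-sided exact permutation p of 2.48e-05 over all pairings, the smallest they can give. Replicates are different patients.

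Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood fit and F test) with the patient as a block, and p-values were adjusted by the Benjamini-Hochberg method over 21536 genes. A gene was called at an adjusted p under 0.05. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 35 lists, and again with an estimated correlation and with fry. There were 36 lists, 19 of programs and 17 of cell types. List scores were means of log2 CPM (prior count 2) over members, and their differences between the samples of a patient were tested by exact two-sided sign flips, 256 in all, so that the smallest p was 0.00781. Spread was tested by all 128 distinct exchanges of labels within patients. Relations between score changes used all 40320 pairings. The tests, lists and most alternatives were set before the data were examined.

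Genes named in the text were the 12 largest rises and 12 largest falls among called genes with a mean CPM of at least 5 and 1 direction in all 8 pairs. Immunoglobulin and T cell receptor segments, sex-linked XIST and Y genes, HLA-DR and HLA-DQ genes and features without a usual symbol, LINC names included, were left out. In each list the rule added the 2 called members with the smallest adjusted p, the 2 with the largest change, and up to 2 called members that moved against the list median. A fixed set of 11 genes was added whatever its result. The rule gave 118 genes, of which the text prints a part, and 3 of them are withheld and not reported here. Genes of near-identical families (KRT6A and KRT6C, DEFB4A, HBA1, the LCE genes) share reads and their values are uncertain.

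Alternatives were no replicate block, RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a stricter filter (CPM of at least 1 in at least 8 samples), 1 surrogate variable (sva 3.50.0) and each patient left out in turn. Added after seeing the data were a fit of protein-coding nuclear genes, a fit with the share of 7 structural RNAs (RN7SL1, RN7SL2, RN7SL3, RN7SK, RPPH1, RMRP and SNORD3A) as a covariate, and a fit without the 2 patients whose tumour library had under 70% protein-coding counts. Exact tests used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. In a test on simulated data for this paired comparison, run on 21536 genes with 200 changed genes, the fit recovered 43.0% of 2-fold and 98.0% of 4-fold changes. Of its 146 calls 5 were false. The changed genes all had a mean CPM of at least 5 and were far fewer than the 4996 genes called here. The shares recovered are therefore not the sensitivity in these data.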

Results

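The series compared cSCC with normal skin of the same patient in 8 patients, 8 tumour and 8 normal libraries, by RNA sequencing. The comparison asks which genes differ between the tumour and its paired control. Total estimated counts, in M (10 to the power 6), were 67.8 ± 27.2 M per tumour library (SD, n = 8) and 58.0 ± 21.9 M per normal library (SD, n = 8). In 2 tumour libraries, of pairs D and F, nuclear protein-coding genes held only 62.3% and 57.0% of the gene counts, against 79.0% to 83.4% in the other 14 libraries. Structural RNAs took 21.4% in that of pair D and 39.7% in that of pair F, so the 2 differed in what else they held. The B and plasma cell list score rose most in pair D, by 5.71, and immunoglobulin segments were not counted among protein-coding genes. Their share of the counts was not measured, and the cause of the low share in pair D was not tested.

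Matrix metalloproteinase genes, SPRR3 and the gene of a parathyroid hormone-related peptide rose in the tumours, while hair follicle keratin genes, ADH1B and HSD3B1 fell. MMP1, an interstitial collagenase (chromosome 11, 102789920 to 102798160), rose from 6.05 ± 10.3 to 482 ± 671 CPM (SD, n = 8), a log2 fold change of 6.47 ± 1.20 (SE), and was higher in 8 of 8 pairs. SPRR3, a cornified envelope precursor (chromosome 1, 153001747 to 153003856), rose from 0.139 ± 0.210 to 53.7 ± 117 CPM (SD, n = 8). Its level varied widely among tumours, and its log2 fold change ran from 6.32 to 8.10 when 1 patient was left out. ADH1B, an alcohol dehydrogenase (chromosome 4, 99304964 to 99352760), fell from 110 ± 99.4 to 2.30 ± 2.55 CPM (SD, n = 8). KRT71, a keratin of the inner root sheath of the hair follicle (chromosome 12, 52543909 to 52553147), had a log2 fold change of -6.61 ± 0.94 (SE).

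Of 21536 genes tested with edgeR, 4996 were called, 2516 higher and 2480 lower in cSCC. With a change of at least 2-fold there were 925 higher and 1554 lower genes, against 1203 higher and 1041 lower with no replicate block, which called 3746 genes in all. Of all genes tested, 3594 (16.7%) moved in 1 direction in all 8 pairs, where independent chance gives 0.781%, and 3094 of these were called. With upper-quartile factors the split was 1816 higher and 3036 lower genes, with 4296 called under both scalings. The count was 3144 without pair B, 2773 with the structural RNA share as a covariate and 3254 without pairs D and F.

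Other large rises were in IL24, a cytokine of the IL-10 family (log2 fold change 4.91, edgeR adjusted p 0.00449), FNDC1 (4.64, adjusted p 0.000510), the serotonin receptor gene HTR7 (4.44, adjusted p 0.000510), PTHLH, which encodes parathyroid hormone-related peptide (4.37, adjusted p 0.00317), the long noncoding RNA MIR31HG (4.37, adjusted p 0.00202) and NEFL, a neurofilament chain (4.28, adjusted p 0.00984). MMP13 and MMP3, a collagenase and a stromelysin, rose by 4.73 and 4.58. MMP10 rose by 4.88, a call that ended when pair A, C or F was left out, with an edgeR adjusted p of up to 0.0643. DEFB4A, a beta-defensin gene with a near-identical copy, had a value of 4.63. Large falls were in the hair keratin KRT85 (-6.05), the steroid enzyme HSD3B1 (-5.52), the inner root sheath keratins KRT25 (-5.12), KRT27 (-5.05) and KRT74 (-4.99), CYP4F8 (-4.96), PI16 of dermal fibroblasts (-4.89) and the keratinocyte chemokine CCL27 (-4.76).

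Some calls of named genes ended under other settings. With no replicate block, where 3746 genes were called, the calls of MMP3, KRT25, HSD3B1, FLG2, LOX, PM20D1, DCD, DCT and PLIN4 ended. With no filter on low counts those of MMP10, MMP13, MMP3, NEFL, HSD3B1, HRNR, FLG2, BTC, CDKN2A, PM20D1, MOGAT1, PLIN4, KRT6A and KRT16 ended. With the structural RNA share as a covariate those of MMP10, MMP13, HSD3B1, FLG2, TAP2, NOTCH2, CDKN2A, EGR3, PM20D1 and MOGAT1 ended. Without pairs D and F those of MMP10, HSD3B1, TAP2, CDKN2A, PM20D1 and PLIN4 ended, and with 1 surrogate variable those of MMP10 and CDKN2A. The highest edgeR adjusted p under any setting was 0.0784 for HSD3B1, 0.172 for PM20D1 and 0.0911 for TAP2, and all kept their direction.

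**Figure D1:**
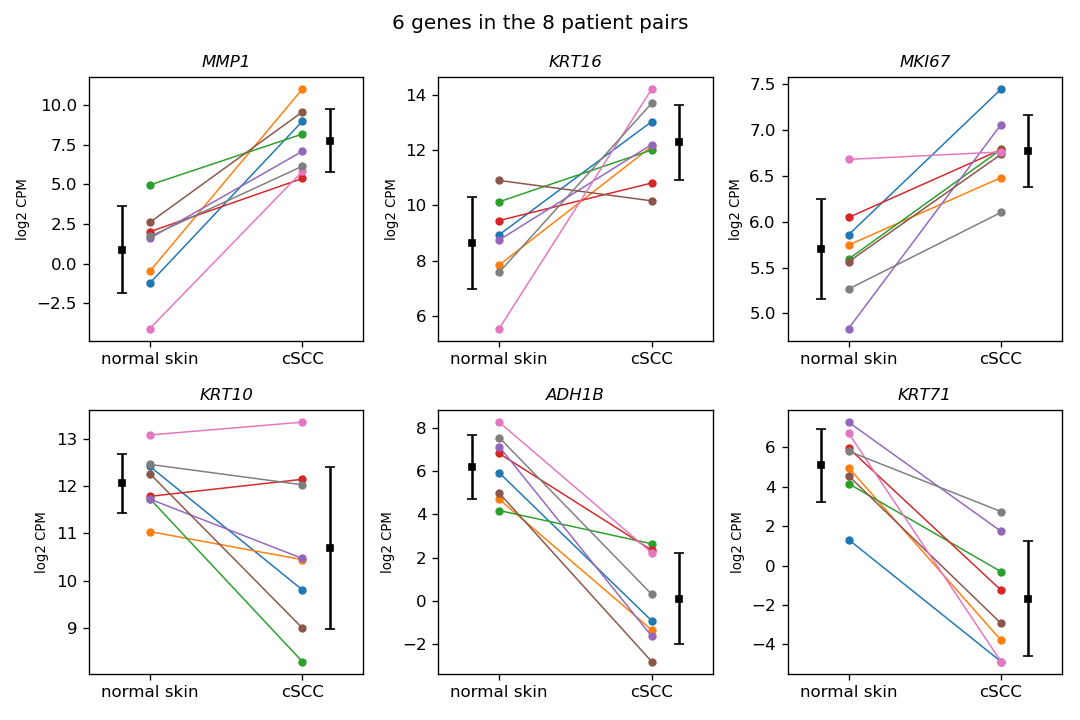
Log2 CPM of 6 genes in normal skin and cSCC. Each line joins the 2 samples of a patient and the black squares and bars are means and SDs of 8 samples. MMP1 was higher and ADH1B and KRT71 lower in the tumour of all 8 pairs, and KRT16 was higher in 7.

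Keratinocyte genes of wounding and hyperproliferation and genes of the basal layer rose, while the barrier genes fell in part. Of 21 wound and hyperproliferation genes 15 rose, 0 fell and 6 did not pass, with 17 higher when adjusted over the list alone. S100A12, a calcium-binding alarmin, rose from 1.38 ± 1.48 to 13.0 ± 9.26 CPM (SD, n = 8), and the protease inhibitor SERPINB4 rose by 1.97 on the log2 scale. The neutrophil list also holds S100A12, and which cells gave its rise was not tested. The stress keratins KRT6A and KRT16 rose by 2.61 and 3.54, higher in 7 of 8 pairs. These calls ended when pair A, B, E or H was left out, with edgeR adjusted p of up to 0.0734 and 0.0766, and KRT17 stood at 1.69 with an edgeR adjusted p of 0.0509. The list rose in camera (adjusted p 2.16e-11; adjusted p = 0.267 with an estimated correlation). Of 14 basal keratinocyte and hemidesmosome genes 8 rose, 1 fell and 5 did not pass, with the same counts adjusted over the list alone. LAMB3, a laminin chain of the basement membrane, rose by 2.54, while the basal keratin KRT15 fell from 637 to 159 CPM on average (n = 8). Camera called this list higher (adjusted p 4.73e-06; adjusted p = 0.267 with an estimated correlation).

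Few cornified envelope and granular layer genes passed, and with both directions among them. Of 25 members 1 rose, 4 fell and 20 did not pass, with the same counts adjusted over the list alone. FLG2, a filaggrin-family protein, went from 5104 ± 4248 to 2229 ± 2071 CPM (SD, n = 8) and was lower in 7 of 8 pairs, a call that ended without pair A, C or E (edgeR adjusted p up to 0.0579). HRNR, which encodes hornerin, went the other way, from 6.33 ± 12.1 to 471 ± 529 CPM (SD, n = 8), a call that ended without pair B (edgeR adjusted p 0.0531). The differentiation keratins KRT1 and KRT10 had log2 fold changes of -1.23 and -1.34 and did not pass (edgeR adjusted p 0.144 and 0.0820). The list was lower in camera with a median of -0.97 (adjusted p 0.0232; adjusted p = 0.649 with an estimated correlation), and this call ended without pair C or F, with adjusted p of up to 0.239. The cornified envelope score changed by -0.50 on average, was higher in 3 of 8 pairs and did not pass (exact sign flips, adjusted p 0.419). Of 15 epidermal lipid barrier genes 6 fell, 0 rose and 9 did not pass, with 7 lower when adjusted over the list alone. ABHD5, a lipase cofactor, fell by 1.78, and the list fell in camera (adjusted p 0.00655; adjusted p = 0.5256 with an estimated correlation). Its score was lower in 6 of 8 pairs and did not pass (exact, adjusted p 0.0798).

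Proteases and stromal matrix genes rose, and genes of resting dermal fibroblasts fell. Of 17 invasion-linked proteases 12 rose and 5 did not pass, with 15 higher when adjusted over the list alone, and the list median was 1.92. ADAM12 and ADAMTS2, which are metalloproteases of the stroma, rose by 1.92 and 1.63 (camera adjusted p 1.36e-10; adjusted p = 0.112 with an estimated correlation). Of 23 tumour-associated fibroblast and matrix genes 13 rose, 1 fell and 9 did not pass, with 17 higher and 1 lower when adjusted over the list alone. COL4A1, a basement membrane collagen, and TNC, an adhesion-modulating glycoprotein, rose by 2.07 and 2.08. COL5A1, a fibrillar collagen, rose from 67.0 to 206 CPM on average (n = 8) and the crosslinking enzyme LOXL2 rose by 1.56, while the related enzyme LOX fell by 0.89. COL11A1 had a log2 fold change of 0.78 and did not pass (edgeR adjusted p 0.327). The matrix list rose in camera (adjusted p 2.55e-08; adjusted p = 0.267 with an estimated correlation). Of 16 resting dermal fibroblast genes 11 fell, 1 rose and 4 did not pass, with 12 lower and 1 higher when adjusted over the list alone. CFD, complement factor D, fell from 120 ± 69.4 to 16.3 ± 9.87 CPM (SD, n = 8) and the matrix protein gene DPT fell by 2.42, while LUM, a collagen-binding proteoglycan, rose by 1.69. This list fell in camera (adjusted p 6.67e-13; adjusted p = 0.0544 with an estimated correlation).

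Proliferation genes rose almost throughout their list. Of 26 cell cycle genes 24 rose and 2 did not pass, with 25 higher when adjusted over the list alone, and the median was 1.41. MKI67, a marker of cycling cells, rose from 55.3 ± 22.3 to 113 ± 31.1 CPM (SD, n = 8), and the spindle gene TPX2 and the nucleotide enzyme gene RRM2 rose by 1.49 and 2.26. Camera gave an adjusted p of 3.05e-18 (adjusted p = 0.267 with an estimated correlation). Of 16 hypoxia and glycolysis genes 6 rose, 1 fell and 9 did not pass, with 7 higher and 1 lower when adjusted over the list alone. The glycolytic genes PKM and ENO1 rose by 1.28 and 1.13 and the glucose transporter gene SLC2A1 by 1.35 (camera adjusted p 0.00127; adjusted p = 0.359 with an estimated correlation). The list score did not pass (8 pairs, exact, adjusted p 0.0547), and the tumour of pair F stood apart in it, at 8.54 against 7.68 for the next tumour in mean log2 CPM. The 16 oxidative phosphorylation genes had 0 calls by edgeR and 0 adjusted over the list alone, with a median of 0.05, a mean of -0.08 and a camera adjusted p of 0.813.

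EGFR family and clock genes fell in part. Of 11 EGFR ligands and receptors 5 fell and 6 did not pass, with 5 lower and 1 higher when adjusted over the list alone. The receptor genes ERBB4 and ERBB3 fell by 3.52 and 0.87, and the ligand gene BTC was at -2.32. The list fell in camera (adjusted p 0.0437; adjusted p = 0.267 with an estimated correlation), and the call ended without pair C, D, E or F (adjusted p up to 0.0946). Of 15 circadian clock genes 4 fell and 11 did not pass, also when adjusted over the list alone, with HLF and CRY2, which encode a clock-output factor and a clock repressor, lower by 2.14 and 1.39 (log2 fold changes -2.14 and -1.39; camera adjusted p 0.00263; adjusted p = 0.267 with an estimated correlation). Of 17 immediate early and tissue handling genes 3 fell and 14 did not pass, also when adjusted over the list alone. The transcription factor genes EGR2 and EGR3 fell by 1.99 and 1.88 (camera adjusted p 0.00504; adjusted p = 0.518 with an estimated correlation). Without pairs D and F the adjusted p of the immediate early list was 0.0865.

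Genes often mutated in this cancer and Notch pathway genes had calls in both directions. Of 18 often-mutated genes 4 rose, 3 fell and 11 did not pass, with the same counts adjusted over the list alone. The median was -0.15, the mean 0.09 and the camera adjusted p 0.991. CDKN2A, which encodes cell cycle inhibitors, rose by 2.61, from 1.47 ± 0.65 to 13.7 ± 9.92 CPM (SD, n = 8), in 6 of 8 pairs. The CDKN2A call ended without pair A, B, D, E, F or G, with an edgeR adjusted p of up to 0.0783. Of 14 Notch pathway genes 1 rose, 3 fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p 0.409), with NOTCH2 lower by a log2 fold change of -0.58. The matched transcripts of NOTCH1 had a value of -0.51 (edgeR adjusted p 0.140).

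Markers of skin appendages, pigment cells and nerve fell. Of 14 hair follicle genes 12 fell and 2 did not pass, also when adjusted over the list alone, with a median of -3.92 (camera adjusted p 5.17e-14; adjusted p = 0.0544 with an estimated correlation). Of 12 sebaceous gland genes 10 fell, 1 rose and 1 did not pass, with 11 lower and 1 higher when adjusted over the list alone. The enzyme genes PM20D1 and MOGAT1 had log2 fold changes of -5.59 and -4.50 (camera adjusted p 2.73e-06; adjusted p = 0.356 with an estimated correlation). Of 10 sweat gland genes 6 fell and 4 did not pass, with 6 lower and 1 higher when adjusted over the list alone. The duct keratin gene KRT77 fell by 3.52, and DCD, which encodes an antimicrobial peptide of sweat, was at -5.66 (camera adjusted p 0.00120; adjusted p = 0.112 with an estimated correlation). Of 9 melanocyte genes 7 fell and 2 did not pass, with 8 lower when adjusted over the list alone. The pigment cell regulator MITF and the melanin enzyme gene DCT fell by 1.68 and 3.25 (camera adjusted p 1.25e-06; adjusted p = 0.267 with an estimated correlation). Of 8 Schwann cell and nerve genes 5 fell and 3 did not pass, with 6 lower when adjusted over the list alone, among them SOX10 (-2.34) and the sodium channel gene SCN7A (-3.84) (camera adjusted p 7.37e-05; adjusted p = 0.219 with an estimated correlation).

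Muscle and fat markers were lower, with fewer members passing. Of 8 smooth muscle genes 3 fell, with LMOD1 at -1.84, and 1 was higher and 6 lower when adjusted over the list alone (camera adjusted p 0.0176; adjusted p = 0.517 with an estimated correlation). Of 6 skeletal muscle genes 2 fell, with MYBPC1 at -3.47, and 4 when adjusted over the list alone (camera adjusted p 0.0210; adjusted p = 0.226 with an estimated correlation). These 6 were the measured part of 10 listed genes and lay near the floor, with MYBPC1 at 1.71 CPM in normal skin and 0.162 CPM in cSCC. Under the stricter filter this list was not tested. Of 9 adipocyte genes 4 fell, also when adjusted over the list alone, with the lipid droplet gene PLIN4 at -3.65 (camera adjusted p 0.0261; adjusted p = 0.518 with an estimated correlation). The smooth muscle call ended without pair D and the adipocyte call without pair D, E or F, with camera adjusted p of up to 0.0651 and 0.0931, and the skeletal muscle call ended without both pairs D and F (0.120). Blood endothelium had 1 lower and 10 uncalled members of 11, or 2 higher and 1 lower when adjusted over the list alone (camera adjusted p 0.456). Lymphatic endothelium had 1 higher and 1 lower member of 7, or 1 higher and 2 lower when adjusted over the list alone, with a median of 0.24, a mean of -0.18 and a camera adjusted p of 0.904. The 3 measured red blood cell genes were too few for a list test, and 1 was lower, also when adjusted over the list alone.

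Interferon response and inflammatory genes rose in part, and most immune cell lists had few called members. Of 21 interferon response genes 10 rose and 11 did not pass, with 12 higher when adjusted over the list alone. ISG15, a ubiquitin-like antiviral protein, and the antiviral enzyme gene OAS2 rose by 2.82 and 1.94 (camera adjusted p 2.72e-07; adjusted p = 0.356 with an estimated correlation). Of 17 inflammatory cytokine and chemokine genes 6 rose and 11 did not pass, with 7 higher when adjusted over the list alone. The neutrophil chemokine gene CXCL5 rose by 4.23 (camera adjusted p 0.00160; adjusted p = 0.356 with an estimated correlation). Of 11 genes of MHC class I presentation 1 rose, the peptide transporter gene TAP2 (0.69), also when adjusted over the list alone (camera adjusted p 0.0253; adjusted p = 0.562 with an estimated correlation). Of 14 macrophage and monocyte genes 3 rose, also when adjusted over the list alone, among them the Fc receptor gene FCGR3A (2.34) (camera adjusted p 0.0210; adjusted p = 0.562 with an estimated correlation). The calls of these last 2 lists ended without pair D or F, with camera adjusted p of up to 0.0969 and 0.0739. Of 7 B and plasma cell genes 1 rose, also when adjusted over the list alone, and the median was 2.20 (camera adjusted p 0.00695; adjusted p = 0.468 with an estimated correlation).

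Some Langerhans and mast cell markers fell, and neither score passed the sign-flip test (8 pairs, exact, adjusted p 0.0643 and 0.0720). Of 10 Langerhans and dendritic cell genes 4 fell and 6 did not pass, with 5 lower when adjusted over the list alone, and CD207, the langerin gene of Langerhans cells, was 69.2 ± 38.5 CPM in normal skin (SD, n = 8) and fell by 1.83 (camera adjusted p 0.000651; adjusted p = 0.356 with an estimated correlation). Of 8 mast cell genes 2 fell, also when adjusted over the list alone, with the receptor gene KIT at -1.42 (camera adjusted p 0.00978; adjusted p = 0.517 with an estimated correlation). Without pairs D and F the adjusted p of the mast cell list was 0.0506, and its call also ended with the structural RNA covariate and with fry. The lists of T and NK cells (1 higher member of 16, 0 when adjusted over the list alone) and of immune checkpoints (1 of 10, also when adjusted over the list alone, the ligand gene CD276 at 1.41) each had a camera adjusted p of 0.0519. The neutrophil list had 3 higher and 1 lower member of 9, or 4 and 1 when adjusted over the list alone (camera adjusted p 0.0939). Among its higher members was S100A12, which the wound and hyperproliferation list holds too. The T and NK cell and checkpoint lists each passed in 8 of 18 alternatives and the neutrophil list in 6, with adjusted p down to 0.000341, 0.00441 and 0.0212 when 1 patient was left out.

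Camera called 27 of 35 lists, 11 higher and 16 lower. With an estimated correlation 0 lists passed, and fry called 18, 8 higher and 10 lower. With the structural RNA share as a covariate 18 passed, 10 higher and 8 lower, and without pairs D and F 18, 9 higher and 9 lower. The covariate ended the calls of cornified envelope, lipid barrier, MHC class I, EGFR, immediate early, macrophage, mast cell, adipocyte, smooth muscle and skeletal muscle lists. Fry ended those of cornified envelope, lipid barrier, MHC class I, immediate early, B and plasma cell, macrophage, mast cell, adipocyte and smooth muscle lists. The stricter filter ended those of MHC class I, inflammatory, EGFR and sweat gland lists, 1 surrogate variable those of cornified envelope, MHC class I, EGFR, macrophage and adipocyte lists, and upper-quartile factors that of EGFR. When the labels of 4 of the 8 pairs were exchanged, camera still called 6 to 20 lists and edgeR 0 genes.

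The list scores gave the direction in each patient. Of 35 lists 14 passed the exact sign-flip test after adjustment, 5 higher and 9 lower in cSCC. Invasion-linked proteases were higher by 2.39 ± 0.97, cell cycle genes by 1.38 ± 0.78, wound and hyperproliferation genes by 2.59 ± 1.68 and basal keratinocyte genes by 1.09 ± 0.73 (SD, n = 8), each in 8 of 8 pairs with an exact p of 0.00781, the smallest possible, and an adjusted p of 0.0249. Tumour-associated fibroblast and matrix genes were higher by 1.02 ± 0.62 in 7 of 8 pairs (SD, n = 8, exact p 0.0156, adjusted p 0.0391). Hair follicle genes were lower (-3.49 ± 0.95), as were resting dermal fibroblast (-2.08 ± 0.63), melanocyte (-1.87 ± 1.24), sweat gland (-1.80 ± 0.97) and Schwann cell genes (-1.74 ± 0.75), each in 8 of 8 pairs (SD, n = 8, exact p 0.00781). EGFR ligand and receptor genes (-0.68 ± 0.37) and skeletal muscle genes (-1.41 ± 0.65) were also lower in 8 of 8 pairs (SD, n = 8, exact p 0.00781). The skeletal muscle genes lay near the floor, with mean scores of 0.97 in normal skin and -0.44 in cSCC. Some differences counted by their sign were very small: -0.0111 for EGFR genes in pair H, -0.0263 for melanocyte genes in pair G and 0.0207 for basal keratinocyte genes in pair D. Sebaceous gland genes (-3.67 ± 2.68) and circadian clock genes (-0.55 ± 0.31) were lower in 7 of 8 (SD, n = 8, exact p 0.0156, adjusted p 0.0391). The interferon response score was higher by 1.41 ± 1.45 in 6 of 8 pairs and did not pass (SD, n = 8, exact p 0.0469, adjusted p 0.0781).

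**Figure D2:**
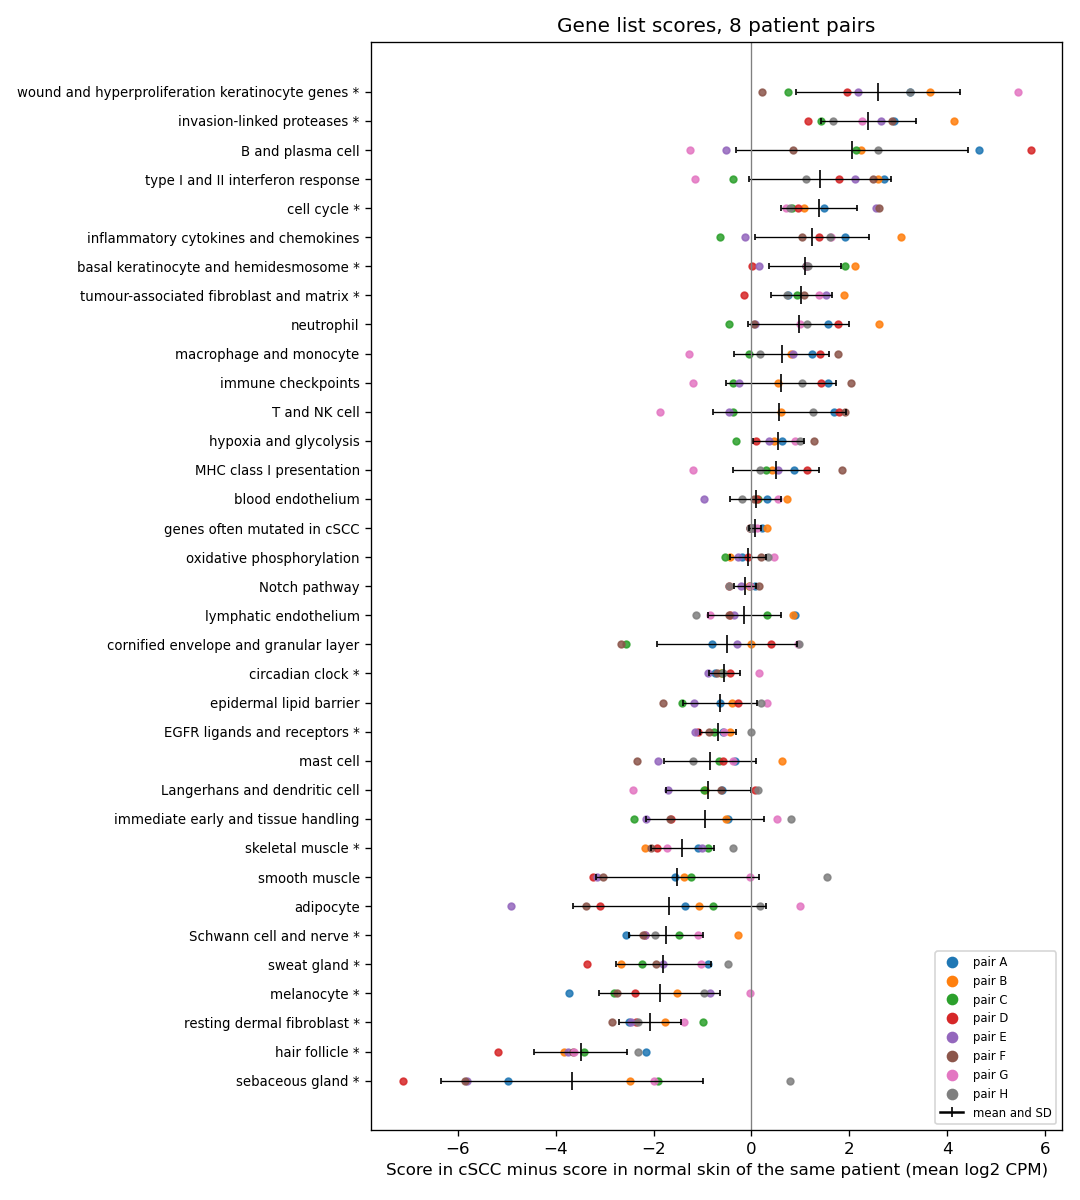
Tumour-minus-normal difference of the mean log2 CPM of each gene list, with 1 coloured point per patient pair and the mean and SD in black. An asterisk marks the 14 lists with an adjusted exact p under 0.05, and the cornified envelope list ran from -2.67 to 0.98 among pairs.

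Tumours differed among themselves more than normal samples did. The median over genes of the log2 ratio of variances, tumours over normal samples, was 0.96, a ratio of 1.94, with a two-sided exact permutation p of 0.0156 over 128 exchanges within patients. Without pairs D and F the log2 ratio was 0.65 (exact p 0.0938, where 0.0312 was the smallest possible).

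Matrix genes and proteases changed together across patients, as did T and NK cell and interferon genes, in a linear measure only. Of 3 relations, that of the fibroblast and matrix list with the proteases had r = 0.76 (n = 8, exact p 0.0283, adjusted p 0.0432) and rho = 0.64 (exact p 0.0962, adjusted p 0.144). Without the 2 pairs farthest from the median r was 0.27, so the relation rested on those pairs. T and NK cell genes against interferon response genes gave r = 0.76 (n = 8, exact p 0.0288, adjusted p 0.0432), rho = 0.52 (exact p 0.197, adjusted p 0.197) and r = 0.73 without the 2 farthest pairs. Cornified envelope against cell cycle genes gave r = -0.47 (n = 8, exact p 0.208, adjusted p 0.208), rho = -0.71 (exact p 0.0576, adjusted p 0.144) and r = -0.68 without the 2 farthest pairs. With medians over members the first 2 of these had r of 0.43 and 0.59 and did not pass (exact permutation, adjusted p 0.292 for both).

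Structural RNAs, which carry no poly(A) tail in the main, took 18.5 ± 9.18% of gene counts in tumours and 13.4 ± 2.46% in normal samples (SD, n = 8), higher in 5 of 8 pairs (exact p 0.125, adjusted p 0.219 over 7 library measures). The labels name polyA RNA and an mRNA kit, which such shares go against, so the library type stayed uncertain. Mitochondrial genes took 0.394 ± 0.134% and 0.760 ± 0.155% (SD, n = 8), lower in the tumour in 8 of 8 pairs (exact p 0.00781, adjusted p 0.0547).

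**Figure D3:**
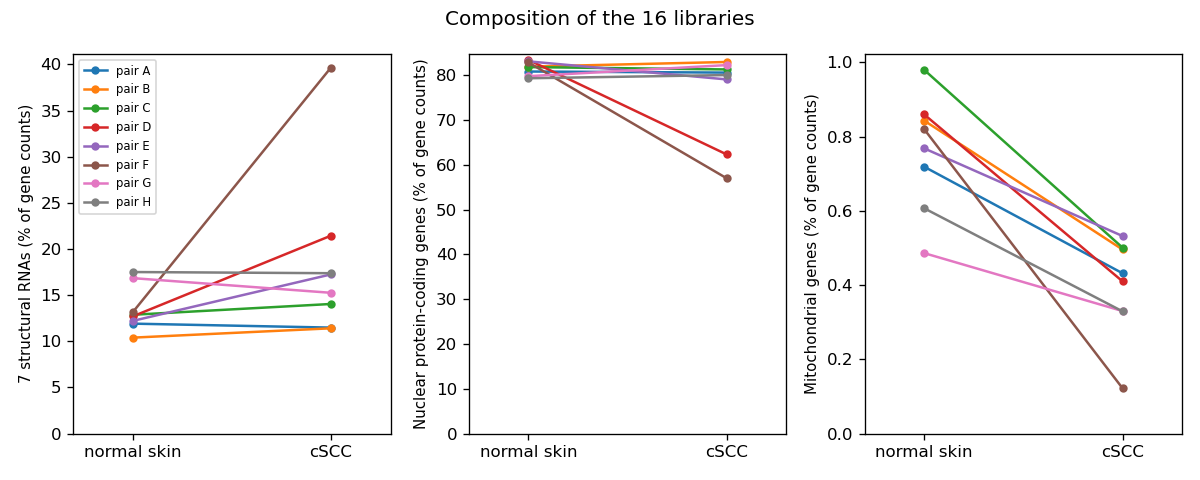
Shares of gene counts, in percent, taken by 7 structural RNAs, by nuclear protein-coding genes and by mitochondrial genes, with a line for each patient pair. The tumour library of pair F had the highest structural RNA share, 39.7%, and the lowest protein-coding share, 57.0%.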

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

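The tests with coding genes only, of fibroblast against endothelium, of the appendage lists and of the basal score were chosen after the results were seen, while those of length and of the SD under coding-gene factors were set before theirs. Single samples far from the other 7 of their group were looked for in 152 groups of values and 12 stood apart, where chance gives about 1 in 20, or 7.60.

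The tumour library of pair F stood apart in its total estimated count (128.9 M against 77.9 M, with M for 10 to the power 6, for the next), in structural RNA share (39.7% against 21.4%), in histone share (0.74% against 0.45%) and in hypoxia and glycolysis genes, whose mean log2 CPM was 8.54 against 7.68 for the next tumour. A fit of protein-coding nuclear genes called 4283 genes, against 4301 protein-coding genes called in the fit of all genes, with 3891 shared. The split moved from 2338 higher and 1963 lower to 1943 higher and 2340 lower. Both fits used TMM factors and kept pair F, so they cannot tell whether a few genes taking most of the counts bear on the calls. With the structural RNA share as a covariate 2773 genes were called, against 4996. Fragmented RNA that favours short transcripts may be part of the cause: across coding genes the change of pair F fell with transcript length (rho = -0.33, genes not being independent), beyond the other pairs, which ran from -0.16 to 0.03. A difference of this tumour itself stays open and was not tested.

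The resting dermal fibroblast score was lower in all 8 pairs. The blood endothelium list did not follow: the difference between the 2 score changes was -2.17 ± 0.63 (SD, n = 8, exact p 0.00781), lower in 8 of 8 pairs. This bears on a lower share of dermis in the tumour samples only if vessels kept their share of the dermis. That was not tested, so the comparison cannot decide. Other lists of cells beneath the epidermis had lower mean scores too, Schwann cell and nerve at -1.74, adipocyte at -1.68, smooth muscle at -1.51 and mast cell at -0.85. Of these only the Schwann cell list passed the exact test after adjustment. The lymphatic endothelium score changed by -0.15 and was higher in 3 of 8 pairs, and the tumour-associated fibroblast and matrix score rose by 1.02. A lower share of dermis stays open as a cause. For the hair follicle, sebaceous gland and sweat gland lists, tumour samples taken without appendages and a loss of appendages in the tumour cannot be told apart, because sampling goes with the group. All 3 scores were lower in the tumour in 7 patients, and in 1 pair the sebaceous gland score was higher.

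The cornified envelope score change ran from -2.67 to 0.98 among pairs. A lower share of keratinocytes in some tumours stays open. The basal keratinocyte score was higher by at least 1.11 in both pairs, C and F, with a cornified envelope fall over 1, but it was higher in all 8 pairs, and the wound keratinocyte score rose least in these pairs (0.74 and 0.23, against 1.96 to 5.45). Making the factors from coding genes did not reduce the differences: the SD of the 8 changes was 1.44 with them and 1.44 in the original. Both were TMM factors and may be close to each other. The SD was not compared under factors of another kind, so a part of the normalization is not excluded. A biological difference among the tumours stays open as a hypothesis.

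The normal library of pair E had a total of 105.7 M, the highest of its group. The normal library of pair G was lowest in the sebaceous gland list (1.59 against 6.01 for the next, in mean log2 CPM), in CYP4F8 (log2 CPM 0.45) and in HSD3B1 (-0.0910). In pair A the lymphatic endothelium list was lowest in both the normal (-0.12) and the tumour library (0.76), and KRT25 was lowest in the normal library (0.77). The circadian clock list was highest in the tumour library of pair G (4.88).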

How the results depend on the processing

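The fits on coding genes, with the structural RNA share and without pairs D and F were chosen after seeing the data. The 4996 called genes became 2773 with the structural RNA share as a covariate, 3254 without pairs D and F and between 3144 (without pair B) and 4493 when 1 patient was left out. The cause was not tested, though the last 2 settings use fewer samples. The remaining paired settings gave 4101 to 7015 genes. With no replicate block 3746 genes were called, 2305 higher and 1441 lower, and 3324 were shared. That unpaired fit ended 25 of the 113 calls among named genes, and 63 of the 113 held under all alternatives that gave a value.

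Camera's 27 called lists became 0 with an estimated correlation, and 14 of the 27 passed in all other alternatives. With the covariate 18 were called, 10 higher and 8 lower, and without pairs D and F 18, 9 higher and 9 lower. No paired list call changed direction without the block, where 27 lists were called as well: cornified envelope (adjusted p 0.121) and macrophage (0.0560) were lost and immune checkpoints (0.0258) and T and NK cells (0.0426) gained. The uncalled lists changed direction in places. For genes often mutated in cSCC camera adjusted p were 0.966 with no replicate block, 0.989 with RLE, 0.947 with upper-quartile factors, 0.767 with no filter, 0.791 with the stricter filter, 0.745 with coding genes, 0.854 to 0.994 when 1 patient was left out, and 0.844 with fry. For oxidative phosphorylation they were 0.905 with coding genes, 0.977 with the covariate, 0.887 without pairs D and F and 0.443 to 0.961 when 1 patient was left out. For lymphatic endothelium they were 0.936 with the covariate, 0.866 without pairs D and F, and 0.587 to 0.981 when 1 patient was left out.

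List scores passed in 14 lists with RLE and with prior count 0.5 and in 11 with medians over members. Without pairs D and F 0 passed by the exact test, with 6 pairs left and a smallest exact p of 0.0312. With medians the uncalled scores of oxidative phosphorylation (0.23), often-mutated genes (-0.20) and blood endothelium (-0.26) changed sign, and the relations fell to 0.59 for T and NK cells with interferon and 0.43 for matrix with proteases. The variance ratio (log2) was 0.65 without pairs D and F, and 0.70 to 1.15 when 1 patient was left out. The simulated test, which had only 200 changed genes, recovered 43.0% of 2-fold changes.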

Other observations

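All tests in this part other than the relations of the histone score, which were set before their results, were chosen after the list results were seen. Of 18 gene families chosen by symbol, 9 of which share 1 to 5 members with the lists, some had calls mostly in 1 direction. Others had calls both ways (claudins 3 higher and 4 lower, WNT ligands 3 and 3, laminins 3 and 2, potassium channels 2 and 5), and of 30 immunoglobulin heavy variable segments 0 were called and 8 had an unadjusted edgeR value under 0.05, with a median of 2.85 (camera adjusted p 0.000369; adjusted p = 0.617 with an estimated correlation). Of 46 genes of proteasome subunits, regulators and assembly factors 23 rose and 0 fell (camera adjusted p 1.04e-08, and 0.297 with an estimated correlation). The assembly factor PSMG1 was at 0.98 and the subunit PSMD2 at 0.75. Of 18 cytosolic aminoacyl tRNA synthetase genes, which charge tRNAs, 11 rose and 0 fell, among them KARS1 (0.59) and YARS1 (0.75) (camera adjusted p 0.000261; adjusted p = 0.287 with an estimated correlation). Of 31 HOX genes 7 rose, with HOXB7 at 3.80 (camera adjusted p 6.21e-05; adjusted p = 0.287 with an estimated correlation). Of 38 cytochrome P450 genes 18 fell and 3 rose, with CYP1B1 at -1.72 and CYP27B1, which activates vitamin D, at 2.40 (camera adjusted p 1.98e-06; adjusted p = 0.221 with an estimated correlation). TUBB3, a tubulin of neurons, was 4.84 CPM in normal skin and 49.7 CPM in cSCC. The 84 genes with symbols of cytosolic ribosomal proteins had 3 higher and 0 lower members, with a median of -0.04 (camera adjusted p 0.715). The 3 were RPL26L1, RPL7L1 and RPL22L1, which are named as ribosomal protein-like genes.

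Of 60 replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail, 30 rose and 0 fell (camera adjusted p 1.10e-12; adjusted p = 0.409 with an estimated correlation), and their score was higher by 1.06 ± 1.07 in 7 of 8 pairs (SD, n = 8, exact p 0.0156). More cells in cycle in the tumour may account for this, as the score change followed that of the cell cycle list (r = 0.87, n = 8, exact p 0.00414, adjusted p 0.00446; rho = 0.81, exact p 0.0218), with r = 0.46 without the 2 farthest pairs. A higher share of RNA without a poly(A) tail in the tumour library may do so too, as the change followed the structural RNA share (r = 0.93, n = 8, exact p 0.00446, adjusted p 0.00446; rho = 0.86, exact p 0.0107), with r = 0.92 without the 2 farthest pairs. Both hypotheses stay open, and 2 relations were tested.

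A gain or loss of a whole autosome shared by the tumours was tested as a hypothesis with camera on the coding genes of the 22 autosomes. The lowest camera adjusted p was 0.209, so 0 autosomes passed, and 2 had an unadjusted camera value under 0.05. Autosome medians reached 0.18, so a small shared shift is not excluded.

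Labels were exchanged within patients in 100 of the 128 distinct ways. Only the real labels, 1 of the 100, gave as many called genes, 4996 against at most 15. A share of 1 in 100 is the smallest that these draws can give. An exchange of pair C alone already gave 0 genes, so the width of the gap does not measure the evidence. As many called lists, 27, came from 2 of the 100, since another exchange reached 27 and the median of the others was 14. That exchange and the next highest kept the real labels in 6 or 7 of the 8 pairs, and exchanges of 4 pairs gave 6 to 20 lists, fewer than the real labels. Camera at the preset correlation thus called lists also where real and exchanged pairs balanced, and correlation among list members, estimated at 0.748 for the cornified envelope list, may be the cause, which was not tested. Splits that put both samples of a patient in 1 group were not run.

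Transcripts without a gene in the annotation were tested by themselves, with the library sizes of the genes. Of 7120 tested, edgeR called 0 (lowest adjusted p 0.0619), while 1269 had an unadjusted edgeR value under 0.05 and limma-voom called 252. In 1 direction in all 8 pairs were 565, where chance gives 55.6. A random sample of 7120 matched transcripts gave 430 edgeR calls, with a common dispersion of 0.42 against 0.69 for the transcripts without a gene and 0.16 for genes. The 0 calls therefore do not show that these transcripts did not change, and none is named here.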
